A study of Homo sapiens with 6 samples.

How the data were processed

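Messenger RNA was measured in 6 libraries, 2 each of PC9, PC9-BrM4 and PC9-AMG cells cultured in MGS. Per the labels' protocols, total RNA of the cancer cells was extracted with TRIzol and sequenced as stranded mRNA libraries (TruSeq Stranded mRNA). Per the submitters' processing notes, HISAT2 2.1.0 and StringTie 1.3.4d were used with the human genome build hg38; the annotation, the read length and any filter are not stated. Libraries of a group are numbered 1 and 2 as in the labels, which do not say what the number stands for. The library names also hold the word mix, whose meaning is not given, so whether RNA of other cells was included is not known.

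Each library has a deposited gene table with 3 values per gene. Per the file headers, Coverage is the mean per-base read coverage of a gene computed by the authors with StringTie, not scaled to depth. Per the file headers, FPKM is the fragments per kilobase and per sequencing depth computed by the authors with StringTie. TPM in the deposited library tables was computed by the authors with StringTie and sums to one fixed total in every library. A deposited table of TPM over all libraries holds 26475 genes, of which 98.9% equal the library tables within 0.001 TPM. TPM of the 1449 genes with more than 1 row in a library table was summed, giving 26485 genes per library. The tables hold no mitochondrially encoded genes.

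No table gives read counts, so the depth is unknown and no counting interval was computed. Coverage at 1 FPKM, one constant for about 60% of the rows of a library, was between 1.40 and 1.86, and at 1 TPM between 0.606 and 0.822, in reads per base. The 100 highest genes held between 25.7% and 29.8% of the TPM of a library.

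The 14627 genes with at least 1 TPM in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1). A mean per group was fitted to all 6 libraries together, with empirical Bayes moderation and a trend of the variance with expression (3 residual and 6.81 prior degrees of freedom). All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes, and the 3 comparisons were PC9-BrM4 against PC9, PC9-AMG against PC9 and PC9-AMG against PC9-BrM4. The tested genes include 515 small-RNA genes, whose TPM from an mRNA library is uncertain. In words, a gene "rose", "fell", was "higher" or "lower" where it was called.

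Gene lists for pathways, lineages, cell types and RNA quality (ribosomal proteins among them), the named-gene rule, the tests and their alternatives were fixed before the data were examined, except where a test is said to be chosen later. Of 41 lists, 36 had at least 3 tested members and were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 36 lists. An adjusted p given with an estimated correlation comes from camera with the correlation estimated from the data, under which 0 lists were called in each comparison. Counts adjusted over the list alone use the Benjamini-Hochberg method on the list's tested members. Named genes are the 8 largest called rises and the 8 largest called falls of a comparison with a mean of at least 5 TPM in the higher group, values that do not overlap between groups and a symbol that is not a clone, locus or small-RNA name. Up to 3 called members per list with the largest differences, and 15 fixed genes, EGFR among them, could be named as well; the text gives a selection of these. Results for some genes are not reported here.

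The changes from PC9 in both derivatives were compared by correlation and covariance across genes, and the genes called in both were counted. Because both use the same PC9 libraries, 100 simulations of unchanged groups with each gene's moderated spread gave the correlation and covariance that the shared libraries alone produce. The covariance was also computed with a different PC9 library for each derivative, with an SE from leaving out each chromosome, a test added after the data were seen. Transcript length and GC content came from the longest GENCODE transcript per symbol, found for 13724 of the tested genes (93.8%). Neighbouring genes were scanned in windows of 50 consecutive tested genes, the median log2 difference of a window being set against the highest of 1000 shuffles of gene order.

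The alternatives were median centring, quantile normalization, TPM rescaled without the 100 highest genes, pseudocounts of 0.1 and 0.5, no filter, a filter at 5 TPM, FPKM, robust moderation, moderation without the trend, the replicate number as a block, only the 4 libraries compared, an estimated correlation and leaving out each library in turn. Removing trends with transcript length and GC content, the TPM of the table over all libraries, and leaving out small-RNA genes were added after the data were seen. Where a library was left out, the lone library of its group is assumed to vary like the other groups. A named gene is said to reverse where its difference changed sign and it was called in the main fit or under that alternative.

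Limma and camera were tested on normal data simulated with each gene's mean over all libraries and its moderated spread. Genes were drawn independently of each other, so camera was not tested on lists whose members vary together. In the data the estimated correlation of a list ranged from -0.0595 (lung lineage) to 0.762 (ribosomal proteins). Of 100 genes planted at a log2 difference of 1, limma called 91, of 100 planted at 2 it called 99, and of 14427 unchanged genes it called 10. A shift of 0.5 planted in the 33 cell cycle genes was found by camera (adjusted p = 2.26e-61, and 0.0137 with an estimated correlation) with 0 other lists called. The scan was tested on random normal differences with the same spread for every gene, and with fewer shuffles than in the analysis. A shift of 0.4 planted in 60 neighbouring genes gave 29 windows above the shuffles, all overlapping the planted genes, and 0 windows without it. Figures were drawn with matplotlib 3.10.9.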

Results

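The data are 6 gene-expression libraries (messenger RNA sequencing) from human lung cancer cells, 2 each of PC9, PC9-BrM4 and PC9-AMG, all cultured in MGS. PC9 is an established lung adenocarcinoma line with an activating EGFR mutation, and the names of the other lines mark them as derivatives of it. The labels expand none of BrM4, AMG and MGS. As far as is known of the study, MGS is a soft culture with mouse glial cells. Values are TPM, length-normalised transcript shares, given as mean ± SD of the 2 libraries of a group (n = 2), and differences are on the log2(TPM + 1) scale. The labels do not say whether the 2 libraries of a group are separate cultures, so every p-value measures the spread between libraries, whatever its source. The files give no read counts and the depth is unknown; a gene at 1 TPM had a per-base coverage between 0.606 and 0.822, and each library listed between 13848 and 14171 genes at 1 TPM or more. Across the 14627 tested genes, the Pearson correlation was 0.986 to 0.990 between libraries of a group and 0.967 to 0.981 between libraries of different groups; genes are not independent replicates.

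The comparison of PC9-BrM4 with PC9 asks which genes differ between a derivative and its parent in the same culture. In PC9-BrM4, 19 of 25 genes of cholesterol synthesis rose and 0 fell, as did 9 and 0 of 16 in fatty acid synthesis, 11 and 1 of 21 in ERK pathway output, and 9 and 2 of 22 both among YAP targets and in the NF-kappaB list. Of the NRF2 targets 8 of 24 fell and 2 rose, and of the ribosomal protein genes, a list fixed beforehand as a sign of RNA quality, 12 of 40 fell and 0 rose. Camera called these lists at the preset correlation but none of them with an estimated correlation (adjusted p between 0.283 and 0.733). The lung lineage factors FOXA1 and GATA6 fell, while the lung lineage list, with 3 of 12 members lower and 1 higher, was not called (adjusted p = 0.0700) except with the replicate number as a block (0.0417) or without PC9 library 2 (0.0385). Limma called 2389 genes, 1446 higher and 943 lower in PC9-BrM4; 617 of them differed by at least 1 on the log2 scale, 340 higher and 277 lower. The split moved with the scaling: median centring gave 917 higher and 1293 lower genes.

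The largest rise in PC9-BrM4 was in CALML5, a calmodulin-like gene of keratinocytes on chromosome 10 (5498695 to 5499570), with 337 ± 60.0 TPM against 3.20 ± 0.213 TPM in PC9 (log2 difference 6.32, adjusted p = 1.66e-08). The imprinted non-coding RNA H19 on chromosome 11 (1995176 to 2001466) reached 42.1 ± 0.907 TPM against 0.0822 ± 0.116 TPM (5.32, adjusted p = 1.05e-06). CPVL, a carboxypeptidase gene on chromosome 7 (28995631 to 29146537), reached 43.4 ± 1.04 TPM against 0.274 ± 0.387 TPM (5.16). KRT81, a hair keratin gene on chromosome 12 (52285913 to 52291515), rose by 4.11 and GGT6 by 3.79. CTAG2, a cancer-testis antigen gene on the X chromosome, was at 12.5 ± 1.27 TPM and was listed at 0 in both PC9 libraries. EIF3CL was at 20.2 and 193 TPM in the 2 PC9-BrM4 libraries and 0 and 6.83 TPM in PC9; it is a near-identical copy of EIF3C. Its value depends on how shared reads were assigned, and its call is uncertain (adjusted p = 0.224 without PC9-BrM4 library 2). JMJD7-PLA2G4B was listed at 0 in PC9 and at 16.4 ± 0.677 TPM in PC9-BrM4, and the overlapping PLA2G4B at 14.9 ± 0.720 TPM in PC9 and 0 in PC9-BrM4. These gene models overlap, so their values depend on how shared reads were assigned. Neither call held when either PC9-BrM4 library was left out (adjusted p between 0.0870 and 0.147).

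The largest fall was in the cell adhesion gene CEACAM6 on chromosome 19 (41755520 to 41772208), from 532 ± 28.7 TPM in PC9 to 8.81 ± 1.67 TPM in PC9-BrM4 (log2 difference -5.77, adjusted p = 1.36e-08). Its neighbour CEACAM5 (41708585 to 41730421) fell by 4.80, from 39.8 ± 3.10 TPM to 0.467 ± 0.0624 TPM (adjusted p = 3.57e-07). AOC1 fell by 3.72, the carboxylesterase gene CES1 by 2.92 and TMEM156 by 2.78. The growth factor gene PTN was at 9.04 ± 1.15 TPM in PC9 and listed at 0 in both PC9-BrM4 libraries. FOXA1, a lung and gut lineage factor, fell from 14.4 ± 0.210 TPM to 1.32 ± 0.722 TPM (log2 difference -2.76).

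In the list of cholesterol synthesis genes, 19 of 25 tested members rose and 0 fell (22 and 0 adjusted over the list alone; camera adjusted p = 2.98e-10, and adjusted p = 0.283 with an estimated correlation). ACAT2 rose by 1.43 and IDI1 by 1.21. In fatty acid synthesis, 9 of 16 rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 0.00411, and 0.733 with an estimated correlation). Called members included SCD at 1.24 and FADS2 at 1.05. Of the ERK pathway output genes, 11 of 21 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.00499, and 0.733 with an estimated correlation). Called members included the receptor gene EPHA4 at 1.72 and the feedback inhibitors SPRY4 at 1.19 and SPRY2 at 0.98. Of the YAP and TEAD targets, 9 of 22 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.0159, and 0.733 with an estimated correlation). Called members included CTGF at 1.34 and THBS1 at 0.93. Of the NF-kappaB targets and inflammatory cytokines, 9 of 22 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.00411, and 0.370 with an estimated correlation). Called members included CXCL1 at 1.94 and CXCL2 at 1.19.

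Of the 24 NRF2 targets, 8 fell and 2 rose in PC9-BrM4 (12 and 2 adjusted over the list alone; adjusted p = 6.49e-06, and 0.283 with an estimated correlation). Called members included AKR1B10 at -2.07, UGDH at -1.07 and GCLM at -0.92. In the hypoxia list, 8 of 28 fell and 2 rose (9 and 3 adjusted over the list alone; adjusted p = 0.0162, and 0.733 with an estimated correlation); LOX fell by 1.29 and ALDOC by 0.93, while the glucose transporter gene SLC2A3 rose by 1.66. In the list of STAT3 targets and acute-phase genes, 4 of 12 fell and 2 rose (6 and 2 adjusted over the list alone; adjusted p = 0.0159, and 0.733 with an estimated correlation). Called members included BCL3 at -1.16. Of the 40 ribosomal protein genes, 12 fell and 0 rose (12 and 0 adjusted over the list alone; adjusted p = 7.12e-11, and 0.733 with an estimated correlation), with a median log2 difference of -0.25 relative to all tested genes. RPS9, with the largest fall among the called members (-0.43), was not called without PC9 library 2 (adjusted p = 0.0882).

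In the list of genes tied to brain metastasis in other models, 5 of 14 rose and 4 fell, and the list was not called (adjusted p = 0.922). ST6GALNAC5 rose from 0.411 ± 0.581 TPM to 5.51 ± 1.11 TPM (log2 difference 2.26), L1CAM by 1.04 and HBEGF by 0.85, while PTGS2 fell by 1.24. The mesenchymal genes S100A4 (1.93), TWIST2 (1.33) and VIM (0.69) rose and SNAI2 fell by 1.47. The list of mesenchymal markers, with 6 of 21 higher and 6 lower, was not called (adjusted p = 0.468). The stress-response gene NUPR1 rose by 3.34, CYP1A1 by 3.44, COL6A3 by 3.06, BST2 by 2.87 and FGFR3 by 1.86, and GDF15 fell by 2.01. EGFR was at 359 and 215 TPM in the 2 PC9-BrM4 libraries and 204 ± 0.152 TPM in PC9, which was not called (log2 difference 0.45, adjusted p = 0.154) but was called without PC9-BrM4 library 2 (adjusted p = 0.0174). ERBB2, ERBB3, CDH1, SERPINI1 and LEF1 were not called either (adjusted p between 0.0711 and 0.964), although ERBB3 was called with median centring (0.0284) and CDH1 without PC9-BrM4 library 2 (0.0304).

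Genes close to each other on a chromosome moved together in places, in stretches found by a scan of neighbouring genes, with medians given relative to all tested genes. A stretch of 76 tested genes on chromosome 7 (17298652 to 33109390) that holds CPVL had a median log2 difference of 0.31. The stretch from 74964818 to 144186081 on the same chromosome, with PTN and AKR1B10, had a median of -0.32 over 347 genes, and the one from 144195321 to 158946192, with AOC1, a median of -0.24 over 74 genes. On chromosome 12, 323 genes between 31647160 and 96953691 had a median of -0.43, and KRT81 rose inside that stretch. RPS9 lies in a lower stretch of chromosome 19 that did not pass the scan once trends with transcript length and GC content were removed.

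The number of called genes fell to 927 without PC9 library 1, 892 without PC9 library 2 and 1195 without PC9-BrM4 library 1, and no named gene reversed direction. The YAP list lost its call without PC9-BrM4 library 1 (adjusted p = 0.108) and the STAT3 list without PC9 library 1 (adjusted p = 0.0503).

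**Figure D1:**
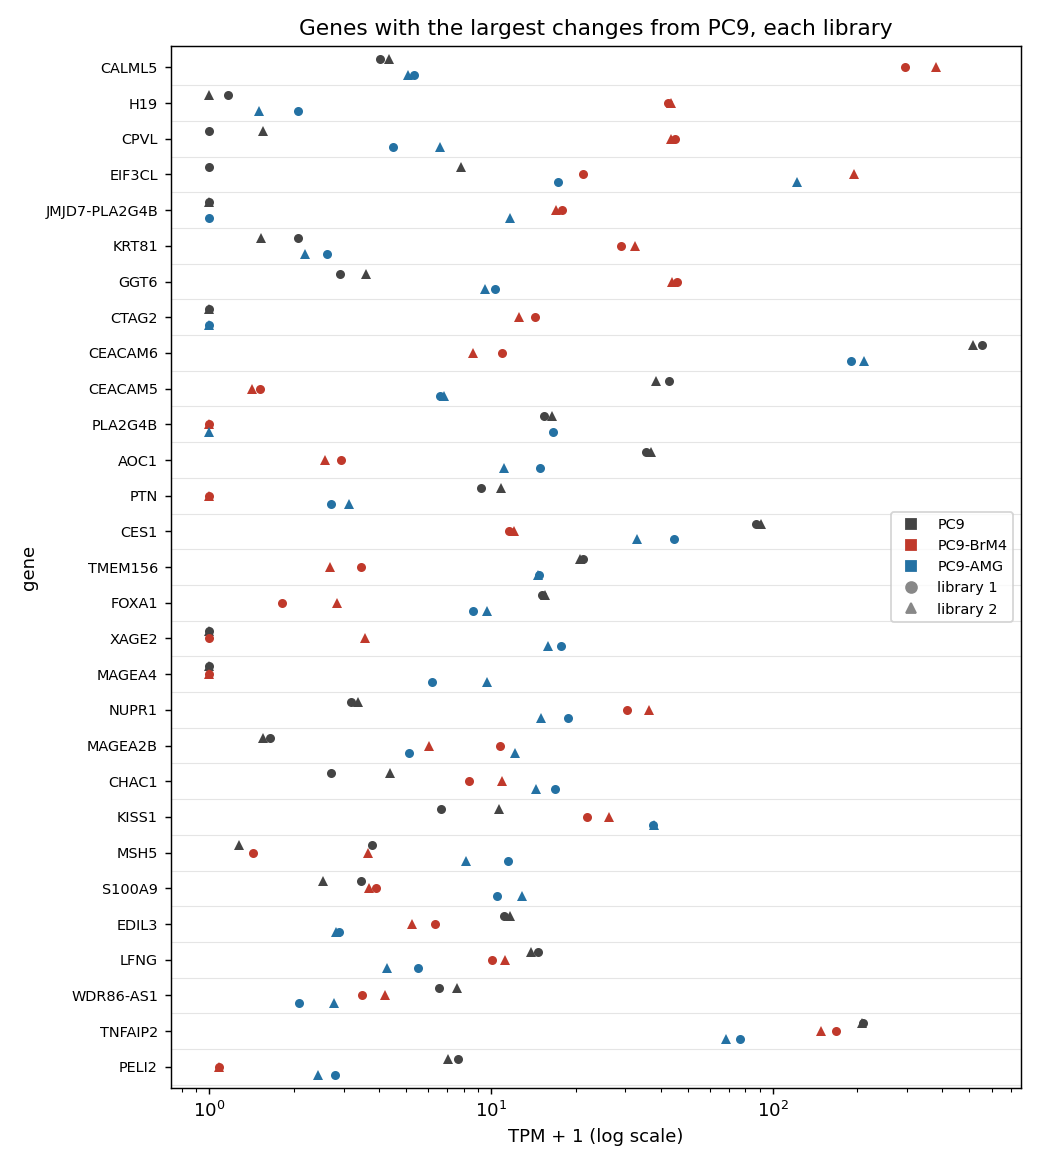
TPM + 1 of each library, on a log axis, for the genes with the largest called rises and falls from PC9 in either derivative; colours mark the groups, circles library 1 and triangles library 2. CALML5 lies far above PC9 in both PC9-BrM4 libraries (337 ± 60.0 TPM) and CEACAM6 far below it (8.81 ± 1.67 TPM).

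The comparison of PC9-AMG with PC9 asks the same of the other derivative. In PC9-AMG, 8 of 24 amino-acid stress genes of the ATF4 list rose and 1 fell, and 2 of 25 cholesterol synthesis, 5 of 40 ribosomal protein (the RNA quality list) and 3 of 33 cell cycle genes rose and 0 fell. In the hypoxia list 12 of 28 genes fell and 1 rose, among laminins and integrins 4 of 25 fell and 0 rose, and among NRF2 targets 7 of 24 fell and 2 rose. Camera called these lists at the preset correlation but none of them with an estimated correlation (adjusted p between 0.598 and 0.794). In PC9-BrM4 against PC9, 10 ATF4 list genes rose and 4 fell, and 8 cell cycle genes rose and 0 fell. Camera did not call either list there (adjusted p = 0.0941 and 0.0518). The vimentin gene VIM fell. Limma called 1096 genes, 537 higher and 559 lower; 165 differed by at least 1 on the log2 scale, 90 higher and 75 lower. Median centring moved the split to 685 higher and 436 lower genes.

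The cancer-testis genes XAGE2 on the X chromosome (52369010 to 52375683) and MAGEA4 (151912889 to 151925170) were at 15.9 ± 1.22 and 6.94 ± 2.46 TPM in PC9-AMG, and both were listed at 0 in PC9 (adjusted p = 0.00212 and 0.00108). XAGE2 was not called without PC9-AMG library 2 (adjusted p = 0.0526). NUPR1 on chromosome 16 (28537341 to 28539174) rose from 2.28 ± 0.128 to 15.9 ± 2.67 TPM (log2 difference 2.36, adjusted p = 0.000312). CHAC1, a glutathione-degrading enzyme gene of the amino-acid stress response, rose by 2.18, the metastasis-suppressor gene KISS1 by 2.17 and S100A9 by 1.97. MAGEA2B (2.31) is a near-identical copy of MAGEA2 and MSH5 (2.14) overlaps a read-through gene model, so their values depend on how shared reads were assigned. Neither call held without PC9-AMG library 2 (adjusted p = 0.0791 and 0.143). CEACAM5 fell from 39.8 ± 3.10 to 5.71 ± 0.170 TPM (log2 difference -2.60, adjusted p = 0.000192). The integrin ligand gene EDIL3 fell from 10.4 ± 0.372 to 1.85 ± 0.0638 TPM. PTN fell by 1.78, the Notch modifier gene LFNG by 1.56, WDR86-AS1 by 1.55, AOC1 by 1.49 and PELI2 by 1.49, the last not called without PC9 library 1 (adjusted p = 0.0528) or PC9-AMG library 2 (0.0585). TNFAIP2 fell by 1.53, from 207 ± 0.603 to 71.5 ± 5.94 TPM.

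Of the 24 ATF4 list genes, 8 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 3.89e-06, and 0.598 with an estimated correlation), NUPR1 and CHAC1 among them; DDIT3 rose by 1.17, a call lost without PC9 library 2 (0.0537) or PC9-AMG library 2 (0.0688). In the list of cholesterol synthesis genes, 2 of 25 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.00366, and 0.598 with an estimated correlation), STARD4 by 0.91 and SQLE by 0.66, and neither was called when any of the 4 PC9 and PC9-AMG libraries was left out (adjusted p between 0.0570 and 0.303). Of the 33 cell cycle genes, 3 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 2.61e-05, and 0.680 with an estimated correlation), namely FEN1 (0.69), AURKB (0.41) and CDC20 (0.37), none of them called when any of these 4 libraries was left out (adjusted p between 0.0552 and 0.342). Of the 40 ribosomal protein genes, 5 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 3.42e-06, and 0.760 with an estimated correlation), with a median of 0.16 relative to all tested genes. The log2 differences from PC9 were lower for longer transcripts (Spearman -0.233 across 13724 genes), and this list was not called once trends with transcript length and GC content were removed (adjusted p = 0.0526). The removal left little trend with length in the group difference (Spearman 0.0191) but raised the one between the PC9-AMG libraries from 0.0592 to 0.233, so its effect on the list is uncertain. Of the 8 tested astrocyte markers, 1 rose, APOE, by 1.76 (2 and 0 adjusted over the list alone; adjusted p = 0.0396, and 0.680 with an estimated correlation); APOE was not called without PC9-AMG library 2 (adjusted p = 0.0522).

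In the hypoxia list, 12 of 28 genes fell and 1 rose (17 and 1 adjusted over the list alone; adjusted p = 4.58e-07, and 0.598 with an estimated correlation). Called members included PFKFB3 at -1.03. Of the TGF-beta targets, 5 of 19 fell and 0 rose (6 and 2 adjusted over the list alone; adjusted p = 0.0378, and 0.760 with an estimated correlation). Called members included ID1 at -0.89 and TGFBI at -0.86. Of the laminins, integrins and basement membrane genes, 4 of 25 fell and 0 rose (4 and 0 adjusted over the list alone; adjusted p = 0.00451, and 0.794 with an estimated correlation). Called members included COL17A1 at -0.65 and LAMA3 at -0.63, neither called when either PC9 library was left out (adjusted p between 0.120 and 0.151). With length and GC trends removed, the adjusted p of this list was 0.0350. Of the NRF2 targets, 7 of 24 fell and 2 rose (12 and 3 adjusted over the list alone; adjusted p = 0.0163, and 0.598 with an estimated correlation). Called members included AKR1C2 at -0.74. In drug efflux and aldehyde dehydrogenases, 5 of 14 fell and 0 rose (6 and 1 adjusted over the list alone; adjusted p = 0.0455, and 0.680 with an estimated correlation). Called members included ALDH3A1 at -0.58, which was not called without PC9 library 2 (adjusted p = 0.0621). In the lung lineage list, 2 of 12 fell and 0 rose (5 and 1 adjusted over the list alone; adjusted p = 0.0396, and 0.598 with an estimated correlation), where MUC1 fell by 0.61 and CAV1 fell by 0.47, neither called when either PC9 library was left out (adjusted p between 0.0929 and 0.306). In glycolysis, 1 of 16 fell and 0 rose (5 and 0 adjusted over the list alone; adjusted p = 0.0378, and 0.709 with an estimated correlation); ENO2 fell by 0.42, a call lost when either PC9 library was left out (adjusted p = 0.216 and 0.212).

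VIM fell from 163 ± 0.506 TPM to 90.1 and 88.7 TPM in the PC9-AMG libraries (log2 difference -0.86). ELF3 fell by 0.92 and FOS fell by 0.71. The EGFR ligand genes AREG and HBEGF rose by 1.03 and 0.81, the latter not called without PC9 library 2 (adjusted p = 0.0763), and PTGS2 fell by 0.74, a call lost when any of the 4 libraries was left out (adjusted p between 0.0844 and 0.252). The complement gene C3 fell by 1.19 and the glutamine transporter gene SLC1A5 rose by 0.74. EGFR was at 172 ± 23.2 TPM and was not called (log2 difference -0.25, adjusted p = 0.459), nor were ERBB2, ERBB3, CDH1, ST6GALNAC5, L1CAM, SERPINI1 and LEF1 (adjusted p between 0.0640 and 0.775), although CDH1 was called without either PC9-BrM4 library (0.0431 and 0.0423). Here too neighbouring genes moved together. FOS and LTBP2 lie in a stretch of chromosome 14 (69050920 to 92121809) with a median of -0.29 over 105 tested genes, and RPL38 in a higher stretch of chromosome 17. VIM lies in a lower stretch of chromosome 10 (15211645 to 32378798) and CDC20 in a higher one of chromosome 1. Neither stretch passed the scan once trends with transcript length and GC content were removed.

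The number of called genes fell to 160 without PC9 library 1, 131 without PC9 library 2, 369 without PC9-AMG library 1 and 152 without PC9-AMG library 2. The ATF4, cholesterol, cell cycle and hypoxia lists kept their calls whichever library was left out. Leaving out 1 library gave adjusted p = 0.104 for laminins and integrins, 0.263 for glycolysis, 0.0863 for TGF-beta targets and 0.0768 for lung lineage (PC9-AMG library 2), 0.129 for astrocyte markers (PC9-AMG library 1), 0.104 for drug efflux (PC9-BrM4 library 1) and 0.0512 for NRF2 targets (PC9 library 1). The lists of TGF-beta targets, glycolysis, NRF2 targets, lung lineage and drug efflux were not called with median centring (adjusted p between 0.0579 and 0.236) or FPKM (0.0823 to 0.218). With only the 4 libraries compared, TGF-beta targets, glycolysis, lung lineage, drug efflux and astrocyte markers were not called (0.0551 to 0.0994), nor were these once length and GC trends were removed (0.0526 to 0.0995). Lung lineage and astrocyte markers were not called with quantile normalization (0.0511 each).

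The comparison of PC9-AMG with PC9-BrM4 asks where the derivatives part. Lower in PC9-AMG were 16 of 25 cholesterol synthesis genes (1 higher), 7 of 16 in fatty acid synthesis (0 higher), 11 of 22 YAP targets (1 higher) and 10 of 22 NF-kappaB targets (1 higher). Of the ribosomal protein genes, the list fixed for RNA quality, 26 of 40 were higher and 0 lower, and of the NRF2 targets 9 of 24 were higher and 5 lower. Here too camera called these lists at the preset correlation only (adjusted p between 0.668 and 0.830 with an estimated correlation). Limma called 2720 genes, 923 higher and 1797 lower in PC9-AMG; 570 differed by at least 1 on the log2 scale, 232 higher and 338 lower. The median log2 difference of all tested genes was -0.13, and -0.01 after quantile normalization; median centring gave 1606 higher and 900 lower genes.

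CEACAM6 was at 199 ± 14.1 TPM in PC9-AMG and 8.81 ± 1.67 TPM in PC9-BrM4 (log2 difference 4.36, adjusted p = 1.05e-07). The gut mucosal gene TFF1 on chromosome 21 (42362282 to 42366535) was at 24.3 ± 3.79 against 1.37 ± 0.406 TPM (3.42, adjusted p = 1.27e-05). APOE was higher by 2.70, XAGE2 by 3.16, the cancer-testis gene SPANXB1 by 2.43 and GNGT2 by 2.39, and MAGEA4 was listed at 0 in PC9-BrM4. H3F3A (3.03) has many processed copies in the genome; its value depends on how shared reads were assigned, and its call is uncertain (adjusted p between 0.0728 and 0.154 when any of the 4 libraries was left out). CALML5 was lower by the widest margin, at 4.20 ± 0.184 against 337 ± 60.0 TPM (log2 difference -6.01, adjusted p = 5.42e-08), followed by H19 at -4.61, CTAG2 at -3.75, MIA and KRT81 at -3.68, RARRES2 at -3.36, SUSD2 at -3.17 and ANKRD35 at -3.16. CTAG2 and RARRES2 were at 12.5 ± 1.27 and 9.25 ± 0.724 TPM in PC9-BrM4, and both were listed at 0 in PC9-AMG.

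Of the cholesterol synthesis genes, 16 of 25 were lower in PC9-AMG and 1 was higher (19 and 1 adjusted over the list alone; adjusted p = 2.05e-05, and 0.668 with an estimated correlation). Called members included ACAT2 at -1.16. In fatty acid synthesis, 7 of 16 were lower and 0 higher (9 and 0 adjusted over the list alone; adjusted p = 0.0270, and 0.830 with an estimated correlation). Called members included SCD at -0.93. Of the YAP and TEAD targets, 11 of 22 were lower and 1 higher (12 and 1 adjusted over the list alone; adjusted p = 0.0117, and 0.830 with an estimated correlation). Called members included MYOF at -0.93 and CTGF at -0.92. Of the NF-kappaB targets, 10 of 22 were lower and 1 higher (10 and 2 adjusted over the list alone; adjusted p = 0.0339, and 0.668 with an estimated correlation). Called members included CXCL1 at -1.83, PTX3 at -1.58 and TNFAIP2 at -1.13. Of the NRF2 targets, 9 of 24 were higher and 5 lower (9 and 7 adjusted over the list alone; adjusted p = 0.0234, and 0.668 with an estimated correlation); AKR1B10 was higher by 1.59 and GCLC was at -0.84. Of the 40 ribosomal protein genes, 26 were higher and 0 lower (31 and 0 adjusted over the list alone; adjusted p = 7.06e-22, and 0.830 with an estimated correlation), with a median of 0.44 relative to all tested genes; RPS16 was higher by 0.79 and RPL28 by 0.72. The log2 differences of this comparison were also lower for longer transcripts (Spearman -0.239 across 13724 genes), and with length and GC trends removed the adjusted p of the ribosomal list was 1.71e-10.

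VIM was at 90.1 and 88.7 TPM in the PC9-AMG libraries against 263 ± 8.43 TPM in PC9-BrM4 (log2 difference -1.54, adjusted p = 8.33e-06). S100A4 was lower by a log2 difference of -1.23, ST6GALNAC5 of -2.43, EPHA4 of -2.04 and FGFR3 of -1.38; L1CAM (-0.67) was not called without PC9-BrM4 library 1 (0.144) or PC9-AMG library 2 (0.0822). FOXA1 was higher by 2.02, GDF15 by 2.09 and DDIT3 by 1.37. CDH1 was lower (-0.80). EGFR was also called (-0.70, adjusted p = 0.0350), but this call was lost under 9 settings. Among these, 3 left out PC9-BrM4 library 1, PC9-AMG library 1 or PC9-AMG library 2. ERBB2, ERBB3, HBEGF, PTGS2, SERPINI1 and LEF1 were not called (adjusted p between 0.0563 and 0.864), although PTGS2 was called with median centring (0.0106). CEACAM6, RPS16 and RPL28 lie in stretches of chromosome 19 whose tested genes were higher as a group, and DDIT3 in such a stretch of chromosome 12. MIA, KRT81 and RARRES2 were lower inside higher stretches of chromosomes 19, 12 and 7. VIM, FOS and TNFAIP2 lie in lower stretches of chromosomes 10 and 14.

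The number of called genes fell to 1024 without PC9-BrM4 library 1, 1782 without PC9-AMG library 1 and 1423 without PC9-AMG library 2. Without PC9-AMG library 2 the YAP (adjusted p = 0.0523), fatty acid (0.0972), NF-kappaB (0.0762) and NRF2 (0.0523) lists were not called. Without PC9-BrM4 library 1 the fatty acid (0.0739) and NRF2 (0.0582) lists were not, and without PC9-BrM4 library 2 the NF-kappaB list (0.160). The NRF2 list was not called with quantile normalization (0.223) or with length and GC trends removed (0.109).

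**Figure D2:**
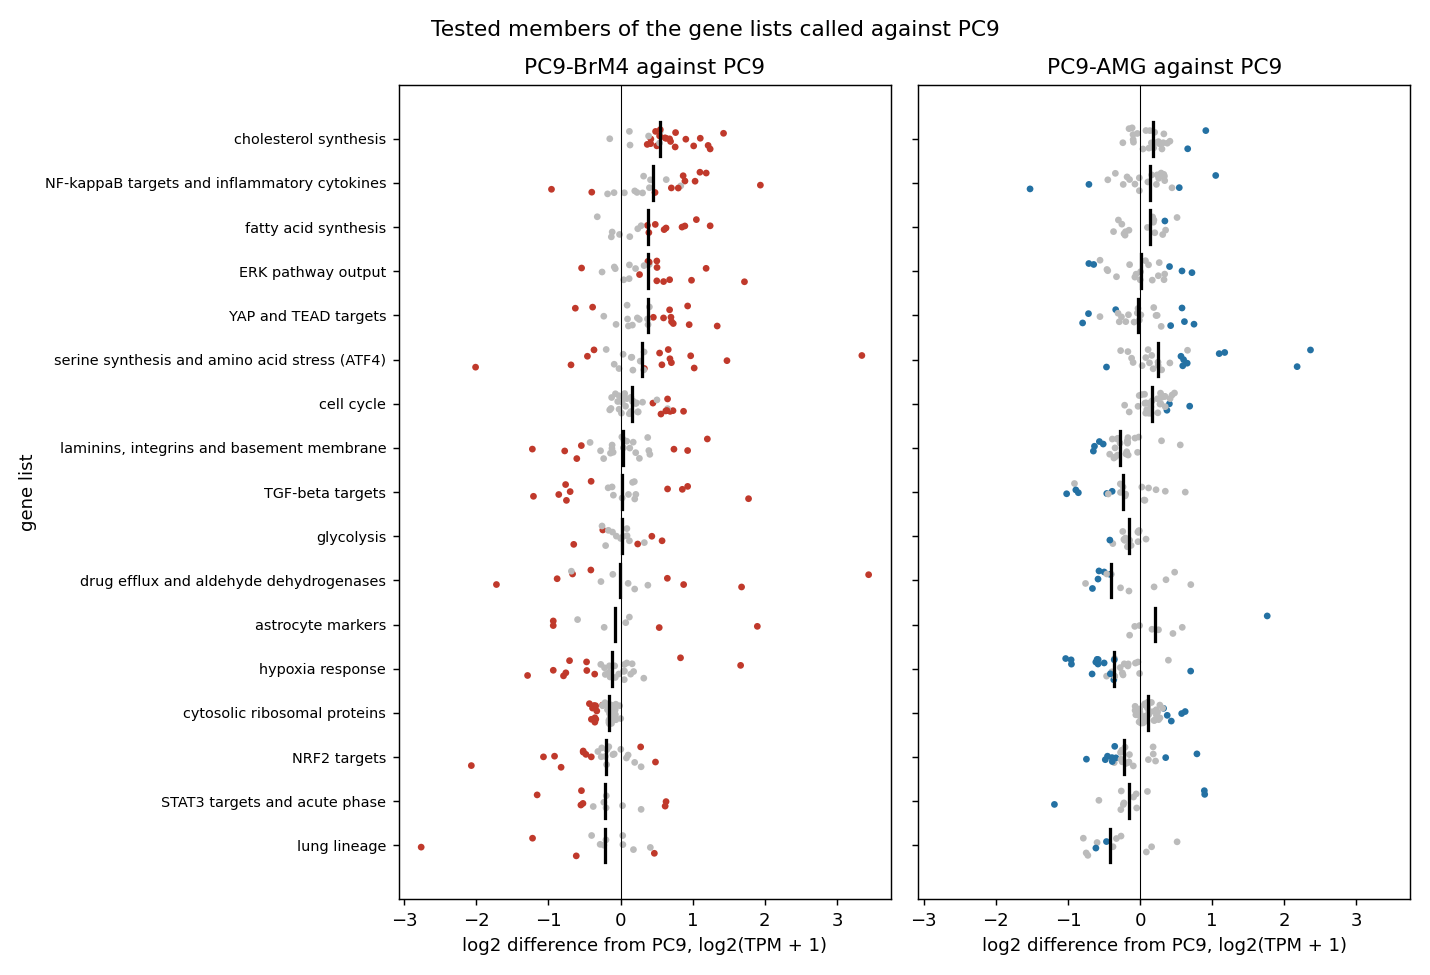
Log2 difference from PC9 of the tested members of the gene lists called in at least 1 derivative against PC9, shown for PC9-BrM4 (left) and PC9-AMG (right), each point being a gene, coloured where called, and each bar the list's median. Of the 25 cholesterol synthesis genes, 19 are called higher in PC9-BrM4 and 2 in PC9-AMG.

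The changes from PC9 in the derivatives were also set side by side, which asks how far they are shared. Across the 14627 tested genes, the log2 differences had a Pearson correlation of 0.442 and a Spearman correlation of 0.394; genes are not independent replicates, and both differences use the same 2 PC9 libraries. In 100 simulations of unchanged groups the shared libraries alone gave a mean Pearson correlation of 0.499, so the correlation by itself does not show a shared change. The covariance was 0.0792, against a highest simulated value of 0.0210. With a different PC9 library for each derivative it was 0.0576 ± 0.00347 and, with the libraries exchanged, 0.0577 ± 0.00382 (± SE, leaving out each of 23 chromosomes). Of the called genes, 247 were higher in both derivatives and 184 lower in both, while 31 were higher in PC9-BrM4 and lower in PC9-AMG and 20 the reverse; these overlaps were not tested, since both sets of calls share the PC9 libraries. Of the 431 genes called in the same direction, 240 had the larger difference in PC9-BrM4 and 191 an equal or larger one in PC9-AMG. CEACAM5, PTN and AOC1 fell in both derivatives, and NUPR1 and CHAC1 rose in both.

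**Figure D3:**
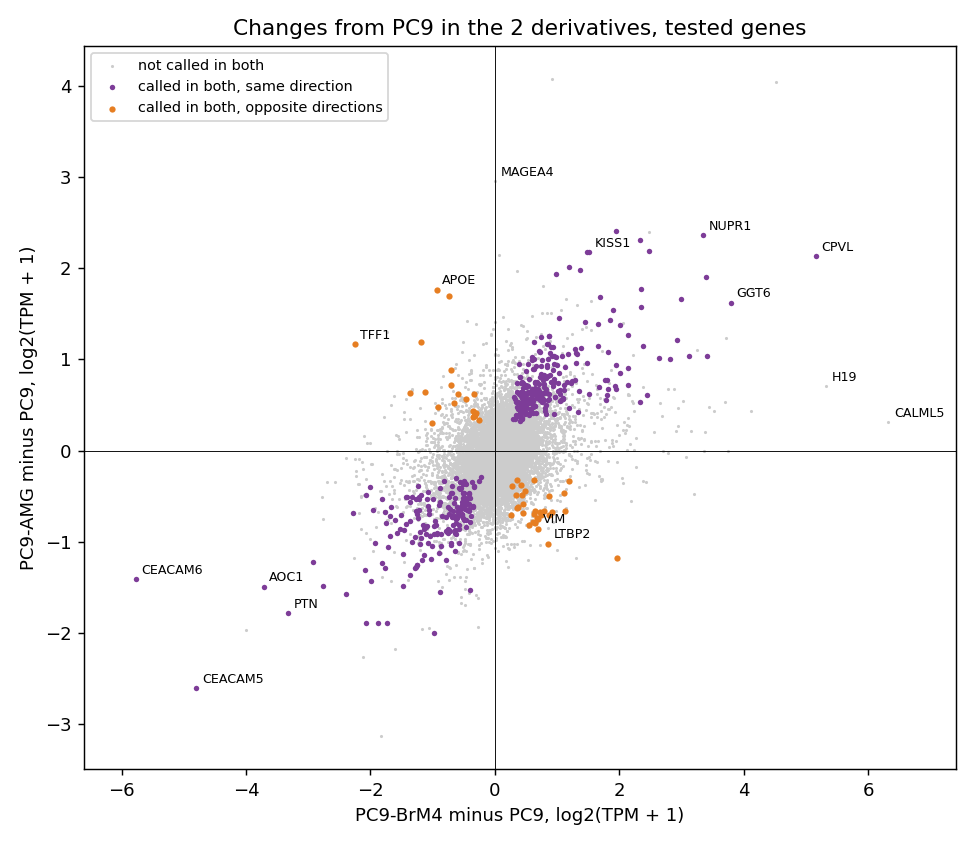
Log2 difference from PC9 of each tested gene in PC9-BrM4 (horizontal axis) and in PC9-AMG (vertical axis), with genes called in both comparisons coloured by direction. The 247 genes higher in both lie in the upper right quadrant and the 184 lower in both in the lower left, with changes of unequal size, such as CEACAM6 at -5.77 and -1.41.

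Of the 27 genes of ionotropic glutamate receptors and glutamate handling, 16 were under 1 TPM in every library and 11 were tested; the list was called in no comparison. Among its members, SLC1A3 was listed at 0 in PC9 and at 2.78 ± 0.931 TPM in PC9-BrM4, and in PC9-AMG SLC1A1 fell by 1.14 and GLUL fell by 0.75, neither called when either PC9 library was left out (adjusted p between 0.0629 and 0.0768).

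Markers of other cell types were mostly near 0. Genes under 1 TPM in every library were 12 of 20 for astrocytes, 12 of 19 for microglia and macrophages, 10 of 16 for oligodendrocytes, 10 of 15 for neurons, 8 of 14 for fibroblasts and pericytes and 9 of 11 for endothelium. Other markers were well above it in these cells, such as CLU at 240 ± 3.89 TPM in PC9. GFAP was listed at 0 in every library. In the lung lineage list 13 of 25 genes were under 1 TPM in every library, NKX2-1 among them, as were 11 of 14 neuroendocrine and 17 of 20 gut and foregut genes. The other fixed lists were called in no comparison, among them epithelial markers, mesenchymal markers, interferon response, p53 targets, heat shock and genes tied to brain metastasis in other models. Under single settings some of the others were called, such as ERBB receptors and ligands in PC9-BrM4 against PC9 with FPKM (adjusted p = 0.0304) and synapse genes without a filter (0.0258). The median, the mean and the test of a list differed in sign for 11 lists in PC9-BrM4 against PC9, 6 in PC9-AMG against PC9 and 11 in PC9-AMG against PC9-BrM4, 0 of them called.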

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

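The tests of glial transcripts and of a different PC9 library for each derivative were chosen only after the results they bear on were seen; the tests of transcript length and of chance shared through the PC9 libraries were chosen before.

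Of the named genes and lists, 15 genes changed from PC9 in opposite directions in the derivatives, each called in both comparisons (limma, adjusted p under 0.05). Each was also called in the direct test of the difference. That difference spans both opposite changes and has the same SE as each, so its call follows from theirs and adds no support. Among those higher in PC9-AMG than in PC9-BrM4 were TFF1 (log2 difference 3.42, adjusted p = 1.27e-05), APOE (2.70), the cancer-testis gene SPANXB1 (2.43) and GNGT2 (2.39), as well as the ribosomal protein genes RPS16 (0.79) and RPL28 (0.72). Lower in PC9-AMG were the TGF-beta binding protein gene LTBP2 (-1.87), the tropomyosin gene TPM2 (-1.58), the pentraxin gene PTX3 (-1.58), VIM (-1.54), ALDH1A3 (-1.37), CYP1B1 (-1.31), HSP90AA1 (-0.99) and FOS (-0.97). These direct calls held under every setting, but several changes from PC9 are less secure. Without 1 library, the calls were lost in 4 of the leave-outs for RPS16, CYP1B1 and PTX3 in PC9-AMG, 3 for HSP90AA1 and 2 for APOE in PC9-BrM4, and 1 for APOE and LTBP2 in PC9-AMG. Leave-outs were run for only some of the changes from PC9, and for none of those of TFF1, SPANXB1, GNGT2, TPM2, ALDH1A3 and RPL28. Of these, TPM2 in PC9-AMG lay close to the threshold (limma, adjusted p = 0.0451). From PC9, TFF1 changed by -2.25 in PC9-BrM4 and 1.17 in PC9-AMG, APOE by -0.93 and 1.76, and VIM by 0.69 and -0.86. RPS16 and RPL28 lie on chromosome 19, VIM on chromosome 10, and LTBP2, HSP90AA1 and FOS on chromosome 14. All of these lie in stretches of neighbouring genes that moved the same way between PC9-AMG and PC9-BrM4. No sample was tested as an outlier, since each group holds 2 libraries.

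EGFR was at 359 TPM in PC9-BrM4 library 1 and 215 TPM in library 2, and many other genes differed between these libraries. The difference of library 1 minus library 2 rose with transcript length (Spearman 0.468 across 13724 genes), from a median of -0.10 among the shortest transcripts (below 1154 bases) to 0.33 among the longest (above 7275 bases); in PC9 and PC9-AMG the correlation with length was 0.0349 and 0.0592, and with GC content it was -0.205 in PC9, -0.328 in PC9-BrM4 and 0.537 in PC9-AMG. EGFR, with a transcript of 9821 bases, lies at the 96.2 percentile of length, and its difference of 0.74 between the libraries fell to 0.38 once the trends with length and GC content were removed. A length bias between the PC9-BrM4 libraries, such as from RNA quality or fragment size, may therefore account for part of the difference in EGFR. The remaining 0.38 and a difference between the cultures stay open, since the labels do not say what separates the libraries.

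The changes from PC9 in the derivatives went together, with a covariance of 0.0792 across genes. Chance shared through the 2 PC9 libraries gave a covariance of at most 0.0210 in 100 simulations, and chance in single PC9 libraries would give none where each derivative is set against a different one, yet the covariance was then 0.0576 ± 0.00347 and 0.0577 ± 0.00382 (± SE). Chance acting on each gene of the PC9 libraries separately is therefore unlikely as the whole source. The Pearson correlation of 0.442 lies below the simulated mean of 0.499 and cannot separate such chance from a shared change. The simulations drew genes independently, and the SE measures the spread between chromosomes, not between libraries. Chance that moves many genes of a library together was thus not covered. A change shared by the derivatives, or a difference of the PC9 cultures from them in handling or sequencing, may each account for the covariance. Both stay open, untested.

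APOE rose in PC9-AMG to 40.8 ± 1.56 TPM, and SLC1A3 was at 2.78 ± 0.931 TPM in PC9-BrM4 and listed at 0 in PC9; both are genes of astrocytes. In PC9-BrM4, however, APOE was lower than in PC9 (log2 difference -0.93, limma, adjusted p = 0.0144), a call among the less secure ones. RNA of glial cells in the culture is a possible source of the higher values. All 8 glial transcripts chosen as a test, among them GFAP, S100B, SPARCL1, MOBP, C1QA, C1QB and TYROBP, were listed at 0 in every library. Of the full marker lists, 5 of 20 astrocyte, 9 of 19 microglia and macrophage and 5 of 16 oligodendrocyte genes were at 0 throughout. The values come from reads aligned to the human genome. Mouse RNA, where present, was counted only as far as it aligns there, for these transcripts and for APOE alike. The zeros could therefore arise with or without mouse glial RNA and cannot decide whether it was the source. Of the 20 astrocyte markers, 8 were tested in these cancer cells, and CLU was at 240 ± 3.89 TPM in PC9 itself. Glial RNA and expression of APOE by the cancer cells thus both stay open, the latter untested. The word mix in the library names is not explained.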

How the results depend on the processing

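Removing trends with transcript length and GC content, the TPM table over all libraries and leaving out small-RNA genes were chosen only after the results were seen; the other settings were chosen before.

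No result for a named gene reversed under any setting run. Sign changes of genes called neither in the main fit nor under that setting were not counted. Of 310 results for named genes, 281 kept their side of the threshold with median centring, 295 with quantile normalization, 298 with a pseudocount of 0.1, 230 without a filter, 249 without the trend and 298 with length and GC trends removed; of the called named genes, 72 of 110, 23 of 81 and 68 of 99 in the 3 comparisons, in the order of the report, were called under every setting. Genes called for PC9-AMG against PC9 (1096) went to 250 without a filter, 325 without the trend and 2523 with length and GC trends removed. The last setting gave 3626 genes for PC9-BrM4 against PC9 (2389), and no filter gave 1799 genes and 10 lists for PC9-AMG against PC9-BrM4 (2720 and 6). Without a filter more genes and more lists are tested. For the other settings the cause was not tested. Lists called for PC9-AMG against PC9 (12) went to 7 with median centring, 7 with FPKM, 7 with only the 4 libraries compared and 6 with length and GC trends removed (the cause was not tested). With an estimated correlation 0 lists were called in PC9-BrM4 against PC9, 0 in PC9-AMG against PC9 and 0 in PC9-AMG against PC9-BrM4. For the NRF2 and NF-kappaB lists the estimated values, 0.00807 and -0.0179, were below the preset 0.01. That argues against a larger correlation as the cause for these lists. In the simulated data, with independent genes, camera's adjusted p of the planted list also rose, from 2.26e-61 to 0.0137. The cause was not tested further.

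Some lists that were not called in a comparison were called there under single settings. In PC9-BrM4 against PC9 these were ERBB receptors and ligands (adjusted p = 0.0304 with FPKM, 0.0393 without PC9 library 2), other receptor tyrosine kinases, synapse and lung lineage (0.0385 each) and microglia markers (0.0484) without PC9 library 2, synapse (0.0258) without a filter, lung lineage (0.0417) with the replicate block, and cell cycle under 4 settings (0.0134 to 0.0495). In PC9-AMG against PC9 it was endoplasmic reticulum chaperones (0.0434 without PC9-AMG library 1). In PC9-AMG against PC9-BrM4 they were ERK pathway output (0.0285 to 0.0496), hypoxia (0.0240 to 0.0386), astrocyte markers (0.0146 to 0.0488) and glycolysis (0.00884 with quantile normalization).

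Without each library in turn, the called genes ranged from 892 to 2383, 131 to 1152 and 1024 to 2886 in the 3 comparisons, the called lists from 8 to 14, 6 to 12 and 3 to 8, and the correlation of the changes from 0.365 to 0.503. The lowest counts came without PC9 library 2 (892 and 131) and without PC9-BrM4 library 1 (1024).

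The split into higher and lower genes turned over with scaling: for PC9-AMG against PC9-BrM4, 33.9% of the called genes were higher as deposited, 64.1% with median centring, 53.8% with quantile normalization and 51.1% with FPKM. For PC9-BrM4 against PC9 it went from 60.5% to 41.5% with median centring. For PC9-AMG against PC9 it went from 49.0% to 61.1% with median centring, 36.0% without PC9-AMG library 1 and 61.9% without PC9 library 1. Taking the replicate number as a block gave 2483, 1298 and 2905 called genes. The deviations of equally numbered libraries correlated at 0.0292, -0.0388 and 0.00267 across genes, so no shift shared by equal numbers was seen. The labels do not say what the number stands for, and these values cannot exclude a weaker pairing.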

Other observations

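The genes named in the next paragraph were chosen only after their values were seen; the scan of neighbouring genes was chosen before, and its repeats between libraries of a group and with length and GC trends removed after.

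Outside the fixed lists, several further genes changed from PC9 in opposite directions in the derivatives. The Wnt antagonist gene SFRP1 was at 12.1 TPM in PC9, 50.3 TPM in PC9-BrM4 and 4.83 TPM in PC9-AMG, a log2 difference of 1.96 in the former and -1.18 in the latter (difference between them -3.13, adjusted p = 4.86e-06). The metallothionein genes MT1X and MT2A were lower in PC9-BrM4 (-0.92 and -1.01) and higher in PC9-AMG (0.48 and 0.30). The creatine kinase gene CKB was higher in PC9-BrM4 (1.13) and lower in PC9-AMG (-0.66), as was the protease inhibitor gene TIMP3 (0.92 and -0.67). The kallikrein gene KLK7, at 264 TPM in PC9, reached 600.3 TPM in PC9-BrM4 (1.18) and was lower in PC9-AMG, at 209 TPM (-0.33).

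Neighbouring genes changed together in places, which the scan measured without testing a cause. In PC9-BrM4 against PC9, 514 of 13494 windows of 50 consecutive tested genes had a median beyond the highest of 1000 shuffles of gene order (0.304), and in PC9-AMG against PC9 241 windows did (0.270). With length and GC trends removed, 495 and 198 windows did. Between the libraries of a group, 0 windows passed in PC9 and 0 in PC9-BrM4, but 21 in PC9-AMG. In PC9-BrM4, 86.1% of the 323 tested genes between 31647160 and 96953691 on chromosome 12 lay below the median difference of all tested genes. Of the 323 genes, 102 were called lower and 6 called higher than in PC9. On chromosome 7, the stretch between 74964818 and 144186081 held 82 lower and 12 higher called genes, and that between 17298652 and 33109390 held 23 higher and 1 lower. In PC9-AMG, the stretches with the most called genes were on chromosome 1 (32741911 to 42959176), with 26 higher and 1 lower, and chromosome 14 (69050920 to 92121809), with 26 lower and 0 higher. No DNA data were analysed here, so copy number was not tested.

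The stretches hold 259 of the genes called in PC9-BrM4 against PC9 (10.8%, with 5.96% of the tested genes inside) and 136 of those called in PC9-AMG against PC9 (12.4%, with 5.20% inside), so most called genes lie outside them. Of the ribosomal protein genes, 2 lie inside the stretches of PC9-BrM4 and 5 inside those of PC9-AMG. Outside them the median difference from PC9, here not relative to all tested genes, was -0.16 over 38 genes and 0.11 over 35 genes. On the same scale it was also -0.16 and 0.11 over all 40 genes, and -0.39 and 0.38 inside the stretches. In PC9-AMG against PC9-BrM4, it was 0.64 over the 10 genes inside stretches and 0.28 over the 30 outside. Of the called ribosomal protein genes, 10 of 12 lie outside in PC9-BrM4, but only 2 of 5 in PC9-AMG.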
